A study of Homo sapiens with 4 samples.

How the data were processed

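RNA was measured by sequencing of polyadenylated transcripts from HaCaT cells, an established line of human keratinocytes, in 4 libraries. Per the labels, 2 libraries came from cells labelled NC and 2 from cells in which a lentivirus was used to overexpress TYMP, the gene of thymidine phosphorylase. The labels do not spell out NC or describe the vector, so NC is used here as a name. Per the labels' protocols, cells were harvested with Trizol after 48 hours and 1.5 µg of RNA per sample entered a NEBNext Ultra library preparation for a NovaSeq instrument. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical.

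The deposited table gave raw read counts and FPKM for 55536 genes by Ensembl identifier, in 1 column per library and unit. The tools HISAT2 and HTSeq 0.13.5 and the genome build GRCh38 are named, without their roles, in the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each FPKM of the authors' table equalled the count divided by a whole-number gene length and the column total, for all 87668 values above 0 at a tolerance of 0.001 bases. FPKM was therefore used only in alternatives. No column was left unmatched to a sample. Coordinates, exon overlaps and GC content came from GENCODE 29 on GRCh38, to which 24934 of 26793 genes with a read matched by identifier (93.1%). Genes that GENCODE 29 also names on sequences outside the primary assembly, which hold the alternate loci and patches, were identified from its transcript names. The match was by gene symbol, so genes given under another symbol, and patches newer than this release, can be missed.

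The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr, TMM scaling, robust dispersion and group as the only term. It tested 14380 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Values per group are CPM scaled by TMM, as mean ± SD over 2 libraries, and log2 fold changes are given with their standard error. An exact permutation of 2 libraries against 2 could not go below p = 0.333, so single genes were tested only in the model fitted across all genes. The replicates were not duplicates: the chi-square per degree of freedom between libraries of a group was 8.15 for NC and 6.4 for TYMP.

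Before the data were examined, 35 gene lists with 883 genes were fixed to fit keratinocytes, thymidine phosphorylase and a lentiviral vector, along with markers of other cell types. The 30 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. camera was repeated with an estimated correlation, a form that rests on the few residual degrees of freedom of 4 libraries. Calls lost there therefore do not show that correlation between genes removed them. The fry test was run beside camera. Examples of genes with few counts, and the gene families, were chosen after their values were seen. Genes changed at least 2-fold that have a copy outside the primary assembly were named as a group. The other genes named in the text were fixed by a rule. TYMP and its neighbours came first, without taking a place among the others. They were followed by the 14 rising and 14 falling genes with the largest log2 fold change among those past the threshold. These had at least 5 CPM in the higher group, both TYMP libraries on 1 side of both NC libraries, and a symbol that was not a clone or locus number. For each list, up to 4 called members by smallest p were eligible, or up to 2 where none was called.

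The procedure was tested on simulated counts with the means, depths and dispersions of these libraries. In the simulated TYMP against NC comparison of 14080 tested genes, it recovered 47.7% of 1.5-fold, 80.6% of 2-fold and 97.0% of 4-fold changes. Of its 185 calls, 16 (8.65%) were false. It called the 1 raised list and 0 of 20 unchanged ones. The simulated genes were drawn independently of each other, so this does not test lists of genes that vary together. Alternatives covered DESeq2 1.42.0, limma-voom, other scalings, other filters, the replicate number as a block, each library left out, FPKM with pseudocounts of 1 and 0.1, and TYMP left out. In the fits without a library, the lone library of a group was assumed to vary like the other group. The FPKM alternatives used the moderated t test of limma on log2 FPKM, without TMM scaling. They kept genes with a mean FPKM of at least 1, so a call lost on FPKM can come from the test as well as the unit. Counts of overlapping genes, and of paralogs with near-identical sequence, are uncertain, because how the authors assigned such reads is not given in the sources used here. Results of some single genes are not reported here.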

Results

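Gene expression was measured in HaCaT keratinocytes to ask which genes change when TYMP is overexpressed. TYMP encodes thymidine phosphorylase, an enzyme that splits thymidine into thymine and a deoxyribose phosphate. There were 2 libraries labelled NC and 2 TYMP overexpression libraries. The total count per library lay between 16209663 and 17000821, and between 21560 and 22236 genes had at least 1 read. Mitochondrially encoded genes took 4.24% ± 0.00406 (SD, n = 2) of the counts in the NC libraries and 5.09% and 4.46% in TYMP replicates 1 and 2.

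Part of the genome was almost empty of counts in all 4 libraries. In the MHC region of chromosome 6, between 28 and 34 Mb on GRCh38, 174 of 200 protein-coding genes (87%) had a mean under 1 CPM. The corresponding share was 18 of 55 (32.7%) between 34 and 38 Mb and 8441 of 19659 (42.9%) in the rest of the genome. HLA-DRA had 0 reads in every library, and HLA-C had 1 read in all 4 together. TUBB, which encodes a beta-tubulin, had 1, 0, 0 and 1 reads. Outside the region, PRPF8 and PSMC4, which encode core components of the spliceosome and the proteasome, also had 0 reads in every library. By contrast, GAPDH had between 27009 and 30101 reads. Levels of such genes were not detectable in these counts, which does not show that they were not expressed. These genes were chosen as examples after their values were seen.

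**Figure D1:**
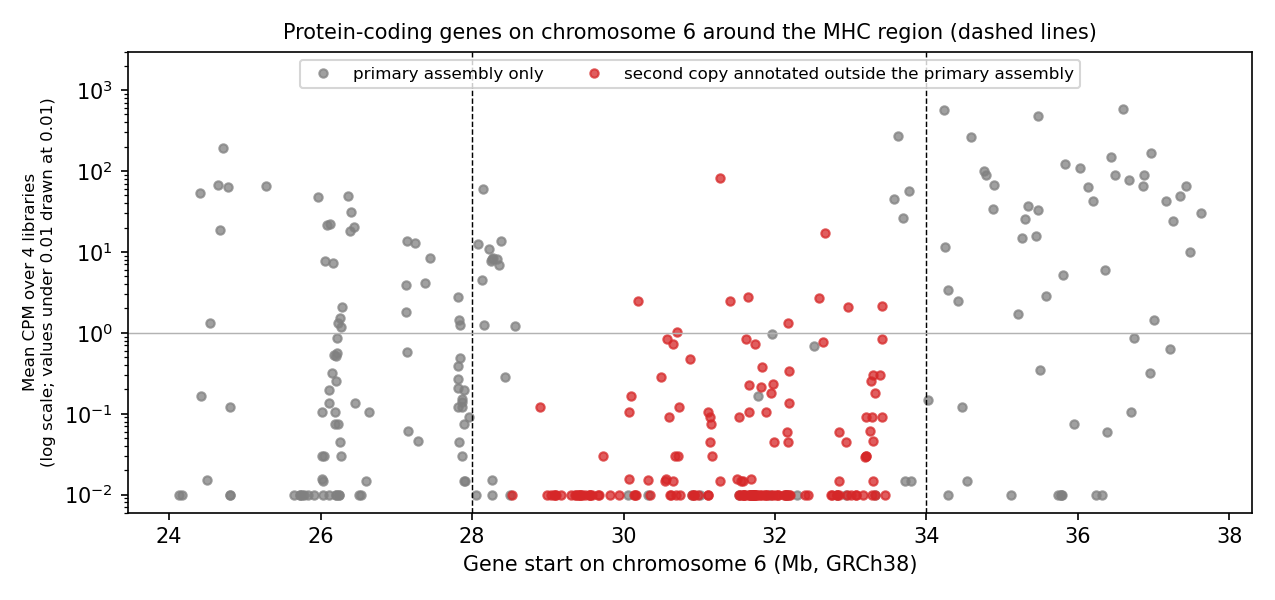
Mean CPM over the 4 libraries (vertical axis, log scale, values under 0.01 drawn at 0.01) of each protein-coding gene by its start on chromosome 6 (horizontal axis, Mb); red points are genes that GENCODE 29 also annotates outside the primary assembly. Between the dashed lines at 28 and 34 Mb, 174 of 200 genes lie under 1 CPM, drawn as a grey line.

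TYMP was higher in the TYMP libraries. It lies on the minus strand of chromosome 22 between 50525752 and 50530056 on GRCh38. It had 281 and 264 reads in the NC libraries and 1221 and 1100 in the TYMP libraries. Its level rose 4.30-fold from 16.3 ± 0.552 to 70.3 ± 7.78 CPM (SD, n = 2 per group), a log2 fold change of 2.10 with a standard error of 0.124 (edgeR adjusted p = 1.47e-06). The counts do not separate a transgene from the endogenous transcript. Among the genes beside TYMP, ARSA, which encodes arylsulfatase A, rose 1.71-fold (adjusted p = 0.0198). CIMAP1B, whose annotated exons overlap those of TYMP, rose 1.98-fold (adjusted p = 0.0352). ADM2, which encodes an adrenomedullin-related peptide, was 2.70-fold lower (adjusted p = 0.0325). Of the 9 tested genes of this list, TYMP among them, 3 rose, 1 fell and 5 were not called (3 and 1 adjusted over the list alone). The camera test called the list higher (adjusted p = 1.49e-05; adjusted p = 0.322 with an estimated correlation), but not once TYMP was left out (adjusted p = 0.124). SCO2, which overlaps TYMP in the annotation, had 6 and 6 reads against 1 and 1 and was not tested. DESeq2 called none of these 3 neighbours (ARSA adjusted p = 0.0667, CIMAP1B 0.144, ADM2 0.178), and on FPKM neither ARSA nor CIMAP1B was called (adjusted p = 0.0575 and 0.0514 with a pseudocount of 1). Their calls were also lost without single libraries. ARSA was not called without TYMP replicate 1 (adjusted p = 0.0903). CIMAP1B was not called without NC replicate 2 (adjusted p = 0.124) or TYMP replicate 1 (adjusted p = 0.0889), nor ADM2 without the same libraries (adjusted p = 0.0888 and 0.124).

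Across the genome, 478 of 14380 tested genes changed, 301 higher and 177 lower in the TYMP libraries. Of these, 136 changed at least 2-fold, 100 higher and 36 lower. Among genes with a mean of at least 5 CPM in the higher group, the largest rises outside TYMP included the suprabasal keratin KRT1, the fatty acid-binding protein FABP4, the invariant chain of MHC class II CD74 and the calgranulin S100A8. The largest falls included the interleukin-1 genes IL1A, IL1R2 and IL1RL1, the interleukin IL6 and the EGF receptor ligand AREG. All 478 genes had both TYMP libraries on 1 side of both NC libraries, which the threshold makes almost certain with so few libraries. Of all tested genes, 43.6% did, where chance gives 33.3%, a difference that was not tested.

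KRT1, on chromosome 12 between 52674736 and 52680407, rose 5.05-fold, from 11.5 ± 0.306 to 57.9 ± 4.15 CPM (SD, n = 2 per group; log2 fold change 2.34 ± 0.124 SE, adjusted p = 8.15e-07). FABP4 rose 5.57-fold, from 1.05 ± 0.138 to 5.88 ± 0.765 CPM (log2 fold change 2.48 ± 0.296 SE, adjusted p = 0.000438). S100A8 rose 3.44-fold, from 11.1 ± 0.962 to 38.1 ± 1.32 CPM (adjusted p = 1.07e-05). SERPINB4, a serine protease inhibitor of squamous epithelia, rose 3.15-fold (adjusted p = 1.68e-05). CD74 rose 3.23-fold, from 6.87 ± 0.622 to 22.2 ± 1.98 CPM (adjusted p = 7.16e-05). The cytokine TNFSF14, the interferon-inducible GTPase GBP2 and the efflux transporter SLC47A2 rose 3.94-fold, 3.89-fold and 3.79-fold. The amine oxidase AOC1, the claudin CLDN8, the semaphorin SEMA6D and the cytochrome P450 CYP4F12 rose 3.57-fold, 3.51-fold, 3.44-fold and 3.39-fold. The log2 fold change of CYP4F12 was 1.76, but 2.42 without NC replicate 1, and CYP4F12 was not called on FPKM with a pseudocount of 0.1 (adjusted p = 0.0597). FLII, an actin-remodelling gene on chromosome 17 between 18244836 and 18258916, rose 6.93-fold, from 7.14 ± 2.11 to 49.5 ± 14.9 CPM (adjusted p = 0.00104). FLII is also annotated on a sequence outside the primary assembly. So are its neighbours MIEF2, with 72, 7, 1 and 0 reads in NC replicates 1 and 2 and TYMP replicates 1 and 2, and TOP3A, with 104, 12, 17 and 79. TBC1D9B rose from 7.42 ± 1.87 to 26.0 ± 3.44 CPM (adjusted p = 0.000116), and MGAT4B, near it on chromosome 5, had 1, 0, 0 and 2 reads.

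IL1A, which encodes interleukin-1 alpha, fell from 59.8 ± 8.37 to 21.8 ± 1.97 CPM (SD, n = 2 per group), 2.75-fold lower (log2 fold change -1.46 ± 0.131 SE, adjusted p = 5.63e-05). The interleukin-1 decoy receptor IL1R2 was 3.54-fold lower (adjusted p = 0.000514) and the interleukin-33 receptor IL1RL1 was 2.67-fold lower (adjusted p = 0.00354). IL6 was 2.57-fold lower (adjusted p = 0.00357). AREG fell from 31.8 ± 0.0957 to 12.2 ± 0.110 CPM, 2.60-fold lower (adjusted p = 7.16e-05). CHAC1, a glutathione-degrading enzyme, was 3.34-fold lower and the YAP target ANKRD1 was 3.04-fold lower. BMPER, NEXN and CPA4 were 2.27-fold, 2.26-fold and 2.24-fold lower. YTHDC1, a nuclear reader of N6-methyladenosine on chromosome 4 between 68310387 and 68350089, fell from 13.4 ± 0.370 to 1.51 ± 0.286 CPM, 8.86-fold lower (adjusted p = 8.13e-06). YTHDC1 and ERMARD, which was 4.36-fold lower, are also annotated on sequences outside the primary assembly. SHMT1, which encodes the cytosolic serine hydroxymethyltransferase, lies next to SMCR8, which had 17, 17, 16 and 11 reads, and was 7.13-fold lower. HPS5 was 3.08-fold lower, with a log2 fold change of -1.62 that moved to -2.29 without TYMP replicate 1. On FPKM, IL1RL1 was not called (adjusted p = 0.0619 and 0.0787 with pseudocounts of 1 and 0.1). DESeq2 did not call HPS5 (adjusted p = 0.052) or NEXN (adjusted p = 0.105), and limma-voom did not call ERMARD (adjusted p = 0.103) or HPS5 (adjusted p = 0.087). Without NC replicate 1, ERMARD (log2 fold change -1.24, adjusted p = 0.126) and HPS5 (-0.99, adjusted p = 0.164) were not called, nor was NEXN without NC replicate 2 (adjusted p = 0.0881).

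**Figure D2:**
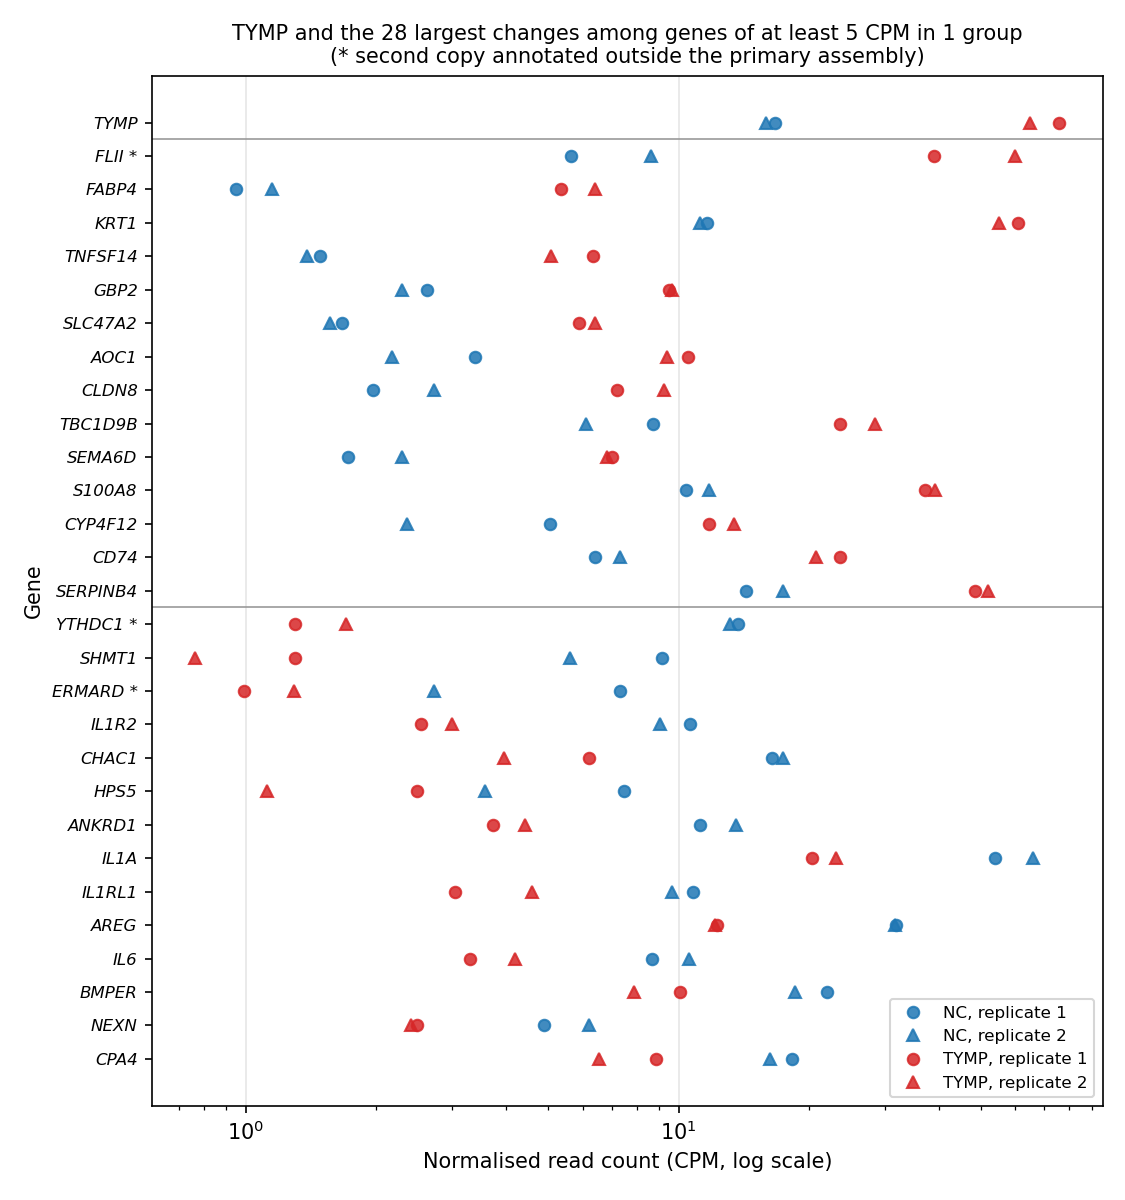
Normalised read count (horizontal axis, CPM, log scale) of TYMP and the 14 rising and 14 falling genes with the largest log2 fold change among those of at least 5 CPM in the higher group; blue marks NC, red TYMP, circles replicate 1 and triangles replicate 2, and asterisks mark genes also annotated outside the primary assembly. TYMP rose from a mean of 16.3 to 70.3 CPM. In each gene both red points lie on 1 side of both blue points, which was a condition for choosing the rising and falling genes.

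Keratinocyte lists were called higher at the preset correlation of camera, although most of their members were not called. Of the 24 tested terminal differentiation genes, 3 rose, 1 fell and 20 were not called (13 and 3 adjusted over the list alone; camera adjusted p = 3.69e-06; adjusted p = 0.322 with an estimated correlation). KRT1 and its partner keratin KRT10, at 1.48-fold, rose, as did the cornified envelope gene SPRR1B. Filaggrin, FLG, a main product of late differentiation, fell from 88.1 ± 0.701 to 56.4 ± 0.00442 CPM (SD, n = 2 per group; adjusted p = 0.00182). Of 28 psoriasis-associated genes, 7 rose, 1 fell and 20 were not called (10 and 1 adjusted over the list alone; camera adjusted p = 1.65e-12; adjusted p = 0.149 with an estimated correlation). S100A9 rose 2.69-fold and the siderophore-binding LCN2 rose 2.07-fold. Of 21 basal keratinocyte and hemidesmosome genes, 3 rose, 2 fell and 16 were not called (5 and 2 adjusted over the list alone; camera adjusted p = 0.00372, higher; adjusted p = 0.376 with an estimated correlation). Keratin KRT15 rose 3.12-fold, from 329 ± 13.1 to 1025 ± 13.4 CPM (adjusted p = 3.42e-07), and KRT5 rose 1.45-fold, while the laminin gene LAMA3 fell. Of 26 epithelial junction genes, 4 rose and 22 were not called (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.322 with an estimated correlation). The 4 were the desmosomal genes DSC2, DSG3, PKP1 and DSC3, between 1.30-fold and 1.45-fold higher. Of 16 Notch pathway genes, 4 rose and 12 were not called (7 higher adjusted over the list alone; camera adjusted p = 9.62e-06; adjusted p = 0.176 with an estimated correlation). The receptor NOTCH3 rose from 5.99 ± 0.108 to 15.7 ± 4.26 CPM (adjusted p = 0.00192).

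Several of these calls were lost under alternatives. The basal list was not called with limma-voom (adjusted p = 0.105), with no filter (adjusted p = 0.138) or on FPKM (adjusted p = 0.178 and 0.175 with pseudocounts of 1 and 0.1), and SPRR1B was not called by DESeq2 (adjusted p = 0.0837). On FPKM with a pseudocount of 1, NOTCH3 (adjusted p = 0.0919), DSC2 (0.0514), DSC3 (0.0707), PKP1 (0.0544) and LAMA3 (0.067) were not called. Nor were the other called Notch genes, DTX4 (0.0506), HES2 (0.0943) and NOTCH1 (0.126). Without TYMP replicate 1, the log2 fold change of HES2 moved from 0.51 to 0.40 and that of NOTCH1 from 0.43 to 0.33. Without NC replicate 2 the basal list (adjusted p = 0.214) and the junction list (adjusted p = 0.0519) were not called, nor were they without TYMP replicate 1 (adjusted p = 0.0899 and 0.147). LAMA3 was not called without TYMP replicate 1 (adjusted p = 0.0582) or TYMP replicate 2 (adjusted p = 0.0967). Without TYMP replicate 2, SPRR1B (adjusted p = 0.0897) and DSC3 (adjusted p = 0.115) were not called, and without TYMP replicate 1 PKP1 was not (adjusted p = 0.0901).

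Some genes of antigen presentation and some interferon-stimulated genes rose, and 0 of either list fell over all genes. Of the 25 listed genes of antigen presentation, 11 could be tested, of which 5 rose and 6 were not called (11 higher adjusted over the list alone). The camera test called the list higher (adjusted p = 1.64e-13; adjusted p = 0.149 with an estimated correlation). CIITA, the master activator of MHC class II genes, rose 1.79-fold from 17.5 ± 1.16 to 31.3 ± 0.818 CPM (SD, n = 2 per group; adjusted p = 0.00208), and CD74 rose as above. On FPKM, CIITA was not called (adjusted p = 0.18 and 0.19 with pseudocounts of 1 and 0.1). Of the 11 tested genes, 5 are also annotated outside the primary assembly, and 7 of the 25 had no read in any library. HLA-DRB1 had 16 and 17 reads in the NC libraries against 63 and 83. Of 49 interferon-stimulated genes, 8 rose and 41 were not called (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.33e-06; adjusted p = 0.176 with an estimated correlation). TRIM22, an antiviral ubiquitin ligase, rose 2.49-fold from 12.7 ± 0.293 to 31.7 ± 0.537 CPM (adjusted p = 9.84e-05). Of 32 apoptosis genes, 5 rose and 27 were not called (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.328). The death ligand TNFSF10 rose 2.56-fold from 58.6 ± 1.88 to 150 ± 5.33 CPM (adjusted p = 3.69e-06) and the inflammatory caspase CASP1 rose 1.74-fold (adjusted p = 0.00134). The median log2 fold change of the apoptosis list was -0.08, while its mean was 0.05 and its test leaned higher. The fry test called it higher (adjusted p = 0.0449), while camera with an estimated correlation did not call it (adjusted p = 0.51).

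Of 27 tested NF-kB-driven inflammatory genes, 4 fell, 2 rose and 21 were not called (5 and 2 adjusted over the list alone; camera adjusted p = 0.0012, lower; adjusted p = 0.195 with an estimated correlation). IL1B fell from 79.2 ± 0.623 to 37.8 ± 0.951 CPM (SD, n = 2 per group; adjusted p = 7.16e-05), and TNFAIP3, an inhibitor of NF-kB signalling, fell from 241 ± 3.93 to 168 ± 1.83 CPM. TNFAIP2 rose from 262 ± 4.04 to 442 ± 30.9 CPM (adjusted p = 0.000189).

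Of 23 tested angiogenic and growth factors, 8 fell, 1 rose and 14 were not called (13 and 1 adjusted over the list alone; camera adjusted p = 2.41e-15, lower; adjusted p = 0.149 with an estimated correlation). Thrombospondin-1, THBS1, an inhibitor of angiogenesis, fell from 1799 ± 25.2 to 830.0 ± 18.3 CPM, 2.17-fold lower (adjusted p = 3.69e-06). The EGF receptor ligand TGFA was 1.60-fold lower (adjusted p = 0.000724) and the matricellular CCN1 was 1.79-fold lower (adjusted p = 0.0027). Of 24 TGF-beta and YAP targets, 7 fell, 2 rose and 15 were not called (12 and 3 adjusted over the list alone; camera adjusted p = 3.69e-06; adjusted p = 0.176 with an estimated correlation). Tissue factor, F3, fell from 654 ± 26.9 to 412 ± 9.82 CPM (adjusted p = 0.000332), while ID1 rose 1.59-fold (adjusted p = 0.000332). Of 26 extracellular matrix and mesenchymal transition genes, 4 fell, 1 rose and 21 were not called (7 and 3 adjusted over the list alone; camera adjusted p = 0.0288, lower; adjusted p = 0.529 with an estimated correlation). TGFB2, N-cadherin (CDH2) and fibronectin (FN1) fell, FN1 from 1557 ± 55.3 to 1108 ± 71.8 CPM, and the collagenase MMP13 rose from 11.1 ± 1.34 to 28.2 ± 0.923 CPM (adjusted p = 0.000178). This list was not called with a filter of 5 CPM in 2 libraries (adjusted p = 0.0614), without NC replicate 1 (adjusted p = 0.168) or TYMP replicate 2 (adjusted p = 0.331).

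Genes of the integrated stress response and immediate early genes were called lower as lists at the preset correlation, while the hypoxia, p53 and heat shock lists were not called. Of 27 genes of the integrated stress response and unfolded protein response, 7 fell and 20 were not called (9 lower adjusted over the list alone; camera adjusted p = 2.19e-09; adjusted p = 0.176 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, was 1.62-fold lower (adjusted p = 0.00143) and PPP1R15A was 1.67-fold lower (adjusted p = 0.00288). Of 25 immediate early genes, 6 fell and 19 were not called (10 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0002; adjusted p = 0.177 with an estimated correlation). The AP-1 component FOSL1 fell from 117 ± 6.17 to 59.9 ± 11.1 CPM (SD, n = 2 per group; adjusted p = 0.000517). Of 21 hypoxia genes, 2 fell, 1 rose and 18 were not called (2 and 1 adjusted over the list alone; camera adjusted p = 0.392). STC2 and VEGFA fell and NDRG1 rose, VEGFA not on FPKM (adjusted p = 0.0711 with a pseudocount of 1). Of 25 p53 targets, 3 fell, 2 rose and 20 were not called (4 and 4 adjusted over the list alone; camera adjusted p = 0.529), with GADD45A and PLK2 lower and TP53INP1 higher. Of 15 heat shock genes, HSPB1 rose 1.71-fold (adjusted p = 0.000318) and 14 were not called (1 higher adjusted over the list alone; camera adjusted p = 0.608). The test leaned lower for the hypoxia and p53 lists, while their median log2 fold changes were 0.01 and 0.03.

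Of 31 tested genes of pyrimidine metabolism, TYMP rose, 2 fell and 28 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.196; adjusted p = 0.444 with an estimated correlation). At the preset correlation the list was called lower with TYMP left out (adjusted p = 0.00538) and with no filter (adjusted p = 0.0123). The 2 were the ecto-5'-nucleotidase NT5E, which fell from 112 ± 4.51 to 61.6 ± 1.05 CPM (SD, n = 2 per group; adjusted p = 0.000169), and the uridine phosphorylase UPP1, which fell from 111 ± 9.66 to 73.1 ± 4.80 CPM (adjusted p = 0.00379). None of 15 pentose phosphate and deoxyribose genes (camera adjusted p = 0.60) and none of 20 glycolysis genes (camera adjusted p = 0.656) was called, over all genes or adjusted over the list alone. Of 28 NRF2 genes, 5 rose, 1 fell and 22 were not called (5 and 1 adjusted over the list alone; camera adjusted p = 0.00372; adjusted p = 0.353 with an estimated correlation). The aldo-keto reductases AKR1C2 and AKR1C3, whose sequences are similar enough for reads to be shared, rose 2.11-fold and 1.88-fold, and the cystine transporter SLC7A11 was 1.63-fold lower. Of 19 fatty acid synthesis genes, 3 rose and 16 were not called (4 higher adjusted over the list alone; camera adjusted p = 0.00183; adjusted p = 0.201 with an estimated correlation). The desaturase SCD rose from 1473 ± 19.3 to 2052 ± 16.5 CPM and its regulator SREBF1 from 125 ± 4.43 to 184 ± 15.4 CPM. Of 24 cholesterol synthesis genes, INSIG1 rose and 23 were not called (2 higher adjusted over the list alone; camera adjusted p = 0.0144; adjusted p = 0.322 with an estimated correlation). Without NC replicate 2 the NRF2 list (adjusted p = 0.12) and the cholesterol list (adjusted p = 0.11) were not called, nor were they without TYMP replicate 1 (adjusted p = 0.0899). INSIG1 was not called without TYMP replicate 2 (adjusted p = 0.0591), and the glycolysis list was called lower without NC replicate 2 (adjusted p = 0.036 at the preset correlation; with all libraries, adjusted p = 0.899 with an estimated correlation). The phosphofructokinase gene PFKP was called lower with no filter (adjusted p = 0.0452) and without NC replicate 2 (log2 fold change -0.43, adjusted p = 0.00164). On FPKM with a pseudocount of 1, SLC7A11 was not called (adjusted p = 0.0711).

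The edgeR fit of all 4 libraries without a block called no cell cycle gene, over all genes or adjusted over the list alone. The mitotic kinesin gene CENPE was called higher without NC replicate 2 (log2 fold change 0.42, adjusted p = 0.0101). The 33 G1/S and DNA replication genes had a median log2 fold change of -0.08 and were called lower as a list (camera adjusted p = 0.0285; adjusted p = 0.322 with an estimated correlation). This call was lost with a filter of 5 CPM in 2 libraries (adjusted p = 0.0865), without NC replicate 1 (median -0.02, adjusted p = 0.276) and without TYMP replicate 2 (median -0.04, adjusted p = 0.13). The 38 G2/M genes had a median of -0.07 and a mean of 0.01 (camera adjusted p = 0.203), and were called lower without NC replicate 1 (adjusted p = 0.0452 at the preset correlation; with all libraries, adjusted p = 0.67 with an estimated correlation). Their median was -0.03 without NC replicate 2 and -0.02 without TYMP replicate 1.

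The same fit called none of 47 cytosolic ribosomal protein genes (camera adjusted p = 0.346), 32 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.239) or 13 mitochondrially encoded genes (camera adjusted p = 0.0981), over all genes or adjusted over the list alone. RPLP2 was called lower with no filter (adjusted p = 0.00686), without NC replicate 1 (log2 fold change -0.59, adjusted p = 2.02e-06) and without TYMP replicate 1 (-0.50, adjusted p = 0.0156). NDUFB8, with 3, 16, 22 and 35 reads, was called higher without NC replicate 2 (3.21, adjusted p = 0.00387). MT-CO2 was called higher when scaled by library size (adjusted p = 0.0436), with no filter (adjusted p = 0.0347) and without TYMP replicate 2 (0.40, adjusted p = 0.00779). MT-ND4 was called higher without NC replicate 1 (0.35, adjusted p = 0.00841) and without TYMP replicate 2 (0.45, adjusted p = 0.0013). The ribosomal list was called lower without NC replicate 2 (adjusted p = 0.021) and TYMP replicate 1 (adjusted p = 0.00669), at the preset correlation (with all libraries, adjusted p = 0.843 with an estimated correlation). The mitochondrial list was called higher by DESeq2 (adjusted p = 0.0464), limma-voom (adjusted p = 0.0259) and on FPKM (adjusted p = 0.0465 and 0.0448), and without NC replicate 1 (adjusted p = 0.0285) and TYMP replicate 2 (adjusted p = 7.63e-06). These calls are at the preset correlation, and with all libraries the adjusted p with an estimated correlation was 0.67. Of 11 replication-dependent histone genes, 0 were called by this fit over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.122), and the list was called higher with no filter (adjusted p = 0.0192) and on FPKM (adjusted p = 0.0155 and 0.0183), at the preset correlation (with all libraries, adjusted p = 0.529 with an estimated correlation).

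Markers of fibroblasts, endothelial cells, leukocytes, melanocytes and embryonic kidney packaging cells had 2, 2, 3, 3 and 4 tested members, too few for a list test, and 0 of them were called by the same fit. Adjusted over the list alone, COL1A1 rose from 4.70 ± 0.587 to 7.32 ± 1.77 CPM, VWF rose from 0.299 ± 0.0817 to 0.938 ± 0.0775 CPM and MITF fell from 20.7 ± 5.09 to 13.9 ± 0.430 CPM (SD, n = 2 per group). MITF was called over all genes with no filter (adjusted p = 0.01) and without NC replicate 1 (log2 fold change -0.80, adjusted p = 0.000192), and moved to -0.31 without NC replicate 2. Without TYMP replicate 1, COL1A1 moved from a log2 fold change of 0.64 to 0.37.

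**Figure D3:**
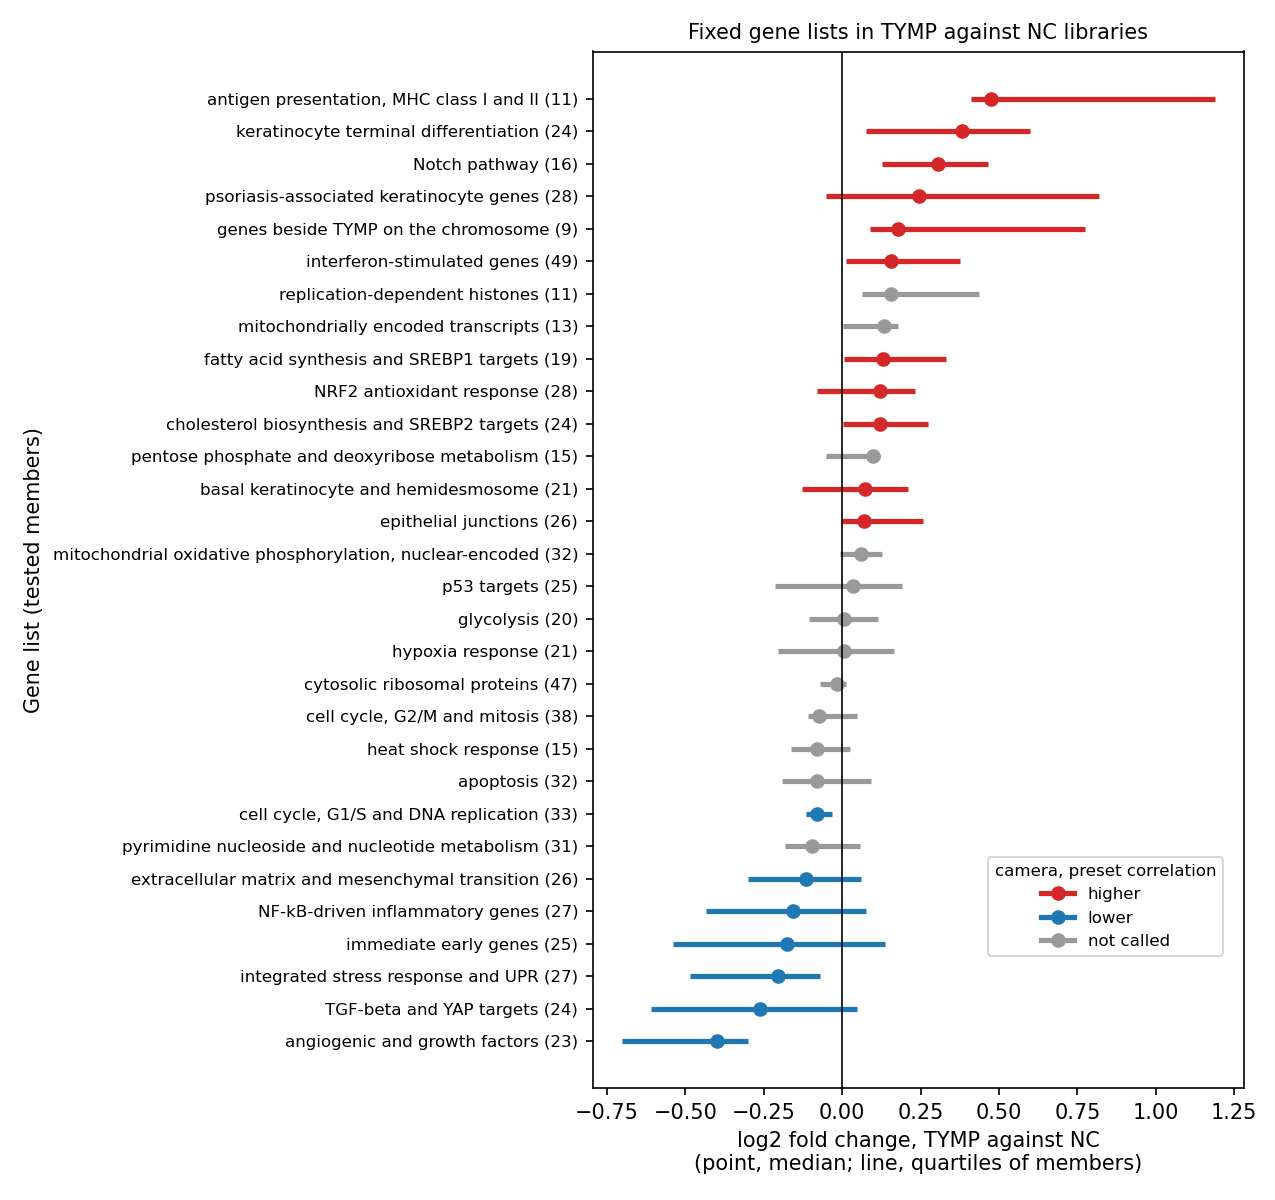
Median (point) and quartiles (line) of the log2 fold change, TYMP against NC (horizontal axis), over the tested members of each of 30 gene lists, with their number in brackets; colour gives the camera call at the preset correlation. The antigen presentation list has the highest median and the angiogenic and growth factor list the lowest. With an estimated correlation, where camera has few degrees of freedom, the lowest adjusted p of any list was 0.149.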

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

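The alternatives that left out genes near regions without counts, or genes with copies outside the primary assembly, were added after the data were seen. The log2 fold change of TYMP lay between 1.90 and 2.21 under its 16 alternatives, past the threshold in all of them. The main test called 478 genes. This became 732 with no filter, 230 at adjusted p under 0.01, and 215 and 210 on FPKM with pseudocounts of 1 and 0.1. The FPKM alternatives differed in test, scaling and unit and kept 10936 genes. Which of these lowered the counts was not tested. DESeq2 called 425 genes, 383 of them shared, and the fits without a library called 393 to 716, with 321 to 430 shared. Without genes that have copies outside the primary assembly, 488 genes were called, 465 of them shared. The 136 genes changed at least 2-fold became 40 and 69 on FPKM with pseudocounts of 1 and 0.1, 150 to 192 without a library, and 11 when glmTreat tested against 2-fold. Of 30 lists, 18 were called with the preset correlation of camera, 15 to 18 without a library, 8 with fry (7 of the 18, and the apoptosis list) and 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05. The estimated-correlation test rests on few degrees of freedom, so its losses need not come from correlation between genes. The angiogenic and growth factor list had an estimated correlation of -0.0404, under the preset 0.01. Its unadjusted camera p still went from 8.03e-17 to 0.0116. The psoriasis list was also under the preset (-0.0288). Other called lists were above it: terminal differentiation 0.189, matrix 0.209 and basal keratinocyte 0.131. For these the preset may understate the correlation. The fry test did not call the terminal differentiation, Notch, integrated stress response or matrix lists (adjusted p = 0.0782, 0.0615, 0.0558 and 0.312). No result was called in both directions. Over all alternatives, the 150 named genes gave 131 losses of a call, 26 gains and 2290 values without such a change. The FPKM alternatives held 36 and 37 of the losses.

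The labels do not say that equal replicate numbers mark a shared batch, and there are only 2 pairs. With the number as a block, 2024 genes were called, 48.4% of them higher, including all 478. Of each cell cycle list, only the 2 genes with the smallest p were followed in this fit. All of them were called, UHRF1, MCM10 and KIF23 lower and CENPE higher. How many other cell cycle genes it called is not given here. Among the few genes followed per list, the blocked fit also called HK2, PFKP and MITF (lower) and H2BC21, H4C8, NDUFA4, NDUFB8 and MT-ND4 (higher). With the block, camera called the mitochondrially encoded list higher at the preset correlation (adjusted p = 0.0154). Without the block, its adjusted p with an estimated correlation was 0.67. With the group as a block, replicate 2 against replicate 1 called 1103 genes. At the preset correlation it called 4 lists, all lower in replicate 2: ribosomal proteins (adjusted p = 4.29e-08), mitochondrially encoded genes (3.11e-07), glycolysis (4.20e-06) and basal keratinocyte genes (0.000467). The median shift of the basal list between replicates, -0.10, exceeded that between groups, 0.07. The differences between replicate 1 and replicate 2 in the 2 groups correlated across genes (not independent replicates) with r = 0.118, and with r = 0.581 over genes of at least 20 CPM. In the latter they followed GC content (Spearman's rho 0.739 in NC and 0.681 in TYMP). The correlation was 0.283 after GC and length trends were removed, just under the bound set beforehand for such trends as the cause. Over resampled genes its interval included the bound, so this stays open. The correlation was 0.581 without the 200 most abundant and the mitochondrially encoded genes. The 3 splits of 4 libraries into pairs are too few for a share under 0.05: the real one called 478 genes and the highest other 7, but the other splits leave the group difference in the spread they are tested against. Small changes can be missed: in the simulation 47.7% of 1.5-fold changes were recovered.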

Other observations

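The gene families in this paragraph were grouped after their values were seen and were not tested for enrichment. Of 20 tested keratins, 8 rose, 1 fell and 11 were not called. KRT13 and KRT4, a keratin pair of non-cornified squamous epithelia, rose 3.14-fold, from 209 ± 24.7 to 658 ± 42.5 CPM, and 3.02-fold, from 21.8 ± 0.793 to 65.8 ± 1.32 CPM (SD, n = 2 per group; edgeR adjusted p = 1.35e-06 and 6.55e-06). KRT19 rose 1.58-fold, and KRT18, a keratin of simple epithelia, was 1.51-fold lower. Of 15 aldehyde dehydrogenases, 4 rose and 11 were not called, among them ALDH3A1, from 13.6 ± 2.40 to 40.2 ± 0.0356 CPM, and ALDH1A1, which makes retinoic acid, from 0.929 ± 0.0328 to 4.60 ± 0.427 CPM. Of 10 clade B serpins, SERPINB3, SERPINB4 and SERPINB13 rose and SERPINB2 fell. Of 13 genes of the interleukin-1 family and its receptors, 4 fell and 9 were not called, and of 6 EGF receptor ligands, 3 fell and 3 were not called. Of these, EREG was not called without NC replicate 2 (log2 fold change -0.49, adjusted p = 0.0891), and nor was KRT14 (adjusted p = 0.157). On FPKM with a pseudocount of 1, EREG (adjusted p = 0.148), KRT14 (0.0863), KRT18 (0.0595) and SERPINB2 (0.0885) were not called. The counts of called keratins, interleukin-1 genes, aldehyde dehydrogenases, serpins and EGF receptor ligands were the same under TMM, library size, upper-quartile and DESeq2 scaling.

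Of the tests in this and the next paragraph, that of the MHC region was chosen after its result was seen, and the comparison of the cell cycle medians with the replicates was added after the medians were seen. Broadly expressed genes had near-zero counts, and a candidate explanation is that reads with a second match on an alternate or patch sequence of GRCh38 were dropped before counting. Among genes of ubiquitous families, 13 of 13 (100%) in the MHC region, which has alternate haplotypes in GRCh38, were under 1 CPM, against 62 of 703 elsewhere (Fisher's exact test, two-sided, p = 6.77e-14). Outside the region, 22 of 38 such genes with a copy annotated outside the primary assembly were under 1 CPM, against 40 of 665 without one (Fisher's exact test, odds ratio 21.2, 95% interval 9.82 to 47.1, p = 1.09e-15). For the 40, no copy was found by gene symbol, so the explanation does not cover them as matched here. Among them are CCT8, with a mean of 0.0149 CPM, and RPS3A, with 0.0764 CPM. POLR1H, inside the region, had 0 reads in every library, and no copy of it was found either. By contrast, B2M and HLA-B have such a copy and had means of 350 and 82.8 CPM. The 13 genes lie in 1 region, and some of the 22 are neighbours, such as NDUFA3 and PRPF31. Genes in these tests are therefore not independent, and the p-values overstate the evidence. The same copies were more frequent among genes changed at least 2-fold, 8 of 136, than among tested genes not called, 202 of 13902 (Fisher's exact test, odds ratio 4.24, 95% interval 1.77 to 8.76, p = 0.00101). The 8 were FLII, YTHDC1, ERMARD, MRNIP, SBNO2, FAN1, DHX16 and HLA-DRB1, and their residual counts may not follow their expression. The comparison was not matched for abundance, and a gene with few reads needs a larger change to be called. Of all protein-coding genes, 81.9% with such a copy were under 1 CPM, against 41.3% without one. For the other 128 changes of at least 2-fold no such copy was found by gene symbol, which can miss renamed genes and newer patches. SHMT1 and TBC1D9B are among these and lie near SMCR8 and MGAT4B, which have such a copy. DHX16 was not called without NC replicate 1 (log2 fold change -3.54, adjusted p = 0.132); it had 34, 13, 0 and 2 reads, too few to size its change. DESeq2 did not call FAN1 (adjusted p = 0.0605), nor was SBNO2 called on FPKM with a pseudocount of 1 (adjusted p = 0.112). Overlap with another gene is not favoured as a cause of the large changes, since 0 of 136 had at least 50% of their exon bases overlapped, against 272 of 13482 (odds ratio 0, upper bound 1.34). Nearness to an empty family gene left the matter open (odds ratio 0.853, 95% interval 0.398 to 1.63), and it does not cover FLII, YTHDC1 or SHMT1.

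At the preset correlation of camera the terminal differentiation list was called higher and the NF-kB and matrix lists lower, but with an estimated correlation 0 of them were (adjusted p = 0.322, 0.195 and 0.529). Against a GC content or gene length trend, 478 of 478 called genes (100%) kept most of their log2 fold change after such trends were removed: the removed trend was at most 0.15, and the smallest called change was 0.31, while 1622 of 13476 genes not called lost at least 50% of theirs. It stays open whether part of the pattern is the difference that separates replicate 1 from replicate 2. The 2 contrasts correlated with r = 0.193 across the 478 called genes (Spearman's rho 0.00147). Over resampled genes the interval of the absolute r was 0.00951 to 0.402. Being of absolute values, it cannot show whether r differs from 0. Slower proliferation, as in a denser culture, also stays open: the G1/S list had a median log2 fold change of -0.0808 and was called lower, the G2/M list was not, and the medians moved by -0.0451 and 0.0584 between replicates; the bound set beforehand, medians above -0.1, was kept with all libraries but not without TYMP replicate 1 (G1/S median -0.102). For cells of another type, only 2 to 4 markers per type had enough reads to be tested. Of these, 0 were called higher over all genes, and COL1A1 and VWF rose adjusted over the list alone. The highest group mean of a tested marker was 7.32 CPM for fibroblasts, 2.72 for endothelial cells and 8.54 for leukocytes. These levels argue against a large share of those 3 types. A small share of them, melanocytes and packaging cells stay open. An effect of TYMP, and a difference between the cells of the groups that arose while they were prepared, are both aligned with the groups. The labels do not say whether NC cells received a vector, so an effect of the lentivirus can be aligned with them too. These were not tested apart.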
